A study of Arabidopsis thaliana with 6 samples.

How the data were processed

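Anthers of Arabidopsis thaliana Col-0 were compared between 3 control and 3 Fe-deficient libraries. The group and the number of each library came from the sample titles. Per the labels, plants grew for 10 days on plates and 18 days in hydroponics before an 18 day treatment, RNA was taken from anthers, and single-end libraries were made with a TruSeq v2 kit. The labels give the iron supply as 50 mM NaFe-EDTA, and the unit could not be checked here. The anther stage is given in the labels by an abbreviation that was not interpreted.

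Trimmomatic 0.35, Salmon 0.12.0 and the TAIR10 build are named in the submitters' processing notes. Per the file headers, the deposited files are Salmon transcript tables, and the authors' estimated counts per transcript are the values used for the tests. Of these, 75.3% were whole numbers, with values of 0 among them. The deposited TPM values, scaled by Salmon for transcript length and library size, sum to the same total in each library and served in alternatives only. Length and effective length per transcript, another measure in the deposited files, served for an alternative with a length offset. How strand was treated in counting is not given in the sources used here, so overlapping antisense genes cannot be told apart. Salmon divides reads between near-identical transcripts, which makes values of paralogs such as IMA1 and IMA2 or the LHCB1 genes uncertain. A short ribosomal RNA transcript, AT2G01020, took between 2.00% and 8.25% of the TPM of a library, which affects TPM more than counts.

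Estimated counts of 41086 transcripts were summed to 33027 loci and rounded to whole numbers. Locus names came from a reference table of the TAIR10.1 assembly, in which 32341 of the loci were found. Coordinates are those of TAIR10.1, 1-based. All 368 distinct list loci were in the files. For 49 of them the reference gave no exact match of the name used here, and none was left out. RPG1 and SWEET8 are the same locus and it stands in the wall and the sugar supply lists, as STP11 does in the late pollen and sugar supply lists.

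Library totals were 18794855, 17474137 and 22710901 estimated counts in controls 1, 2 and 3, and 16818176, 19408488 and 21666427 in Fe-deficient 1, 2 and 3. Loci of ribosomal RNA took between 0.272% and 1.62% of the counts. TMM factors were between 0.884 and 1.06. No pair among the 15 pairs of libraries was identical. Chi-square per degree of freedom between libraries of 1 group was 27.7 to 133, so no pair agreed within counting noise and none was merged. This does not show that the libraries came from separate plants.

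The test was edgeR 4.0.16's quasi-likelihood test with TMM factors after filterByExpr, with group as the single term and Benjamini-Hochberg adjustment at 0.05. R 4.3.3, limma 3.58.1 and DESeq2 1.42.0 were used besides. Per-gene levels are CPM on TMM-scaled library sizes. Python 3.11.15 and matplotlib 3.10.9 drew the figures. Gene lists were tested with camera at a preset correlation of 0.01, over lists with at least 5 tested members (20 of 22), with an estimated correlation and fry beside it. List medians per library used log2 CPM with a count of 0.5 added, less the mean of the 3 controls. A value of 0 counts was given a floor of 3 counts, and floors cover counting error only.

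The groups, the tests, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 2 CPM, where all 3 libraries of 1 group lay above all 3 of the other. It further named up to 4 members past the threshold from each list, a fixed set of iron genes, and up to 2 members with the lowest unadjusted p from lists with none. No gene met the first parts, so 61 genes were named by the others, of which 57 were tested. AP1 and the light-harvesting genes LHCA4, LHCB1.1, LHCB1.2 and LHCB2.1, and CALS5, are named besides them and were chosen after their values were seen, as were genes of the closing observations. Alternatives were other scalings, low-count filters, a length offset, limma on TPM, DESeq2, voom, a replicate number as block, and each library left out. Added later were DESeq2 without Cook's filter, a pollen covariate with and without Fe-deficient 3, and fits without doubted libraries.

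The procedure was tested on simulated data for Fe-deficient against control with the gene-wise spread of these libraries (21060 genes, 50 changed at each fold size). It recovered 4% of 2-fold, 84% of 4-fold, 80% of 8-fold and 96% of 16-fold changes, with 8 false calls among 140. In a simulation of 2 shifted lists among 20, both were called by camera and 1 unshifted list was called as well. Both simulations drew each gene independently, unlike the real libraries, where genes of a list can move together. A rate of false list calls can therefore not be read from them. The recovery rates of single genes may not hold for the real libraries either. A lack of calls there does not show that large changes are absent. Among the real libraries, other splits into 3 and 3 gave 4 to 9 called lists.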

Results

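RNA was sequenced from anthers of wild-type Arabidopsis thaliana (accession Col-0). The plants had first grown for 28 days with iron and were then kept for 18 days either with iron supplied as NaFe-EDTA (control, 3 libraries) or without it (Fe-deficient, 3 libraries). The labels do not say whether libraries of a group came from separate plants or cultures. The p-values therefore measure only the spread between these libraries, which may be technical. Estimated counts summed to between 16818176 and 22710901 per library, and between 24444 and 25208 genes had at least 1 count in a library. No pair of libraries held identical values. The question the design poses is which anther transcripts differ when iron is withheld.

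The iron-deficiency genes bHLH38, bHLH39, bHLH100, bHLH101, IMA1, IMA2, IMA3, BTS, OPT3 and FRO3 were very high in 1 of the 3 Fe-deficient libraries, Fe-deficient 3. In Fe-deficient 2 the bHLH and IMA genes among them were close to control levels, and in Fe-deficient 1 the IMA genes and OPT3 were above all controls, far below their levels in Fe-deficient 3. FRO3 was slightly above all controls in both. The root uptake gene IRT1 was below all controls in Fe-deficient 3 (12.9 CPM against at least 22.4 CPM). FIT, a regulator of iron uptake, lay within the control range there. FRO2 (3.40 CPM) was just above the highest control there (3.09 CPM) and was at 16.3 CPM in Fe-deficient 1. Below all controls in each Fe-deficient library were 18 of 26 pollen wall genes and 9 of 17 regulators of the anther and the tapetum, its nursing cell layer. An exception, chosen after its values were seen, was the wall gene CALS5, a callose synthase, at 635, 482 and 178 CPM in Fe-deficient 1, 2 and 3 against 90.4, 201 and 232 CPM in the controls. Both lists were called lower by camera, with an adjusted p of 0.525 when the correlation was estimated. Late pollen genes were higher in Fe-deficient 1 and Fe-deficient 2. No single gene passed the threshold by edgeR's quasi-likelihood test. Of 21267 genes tested, 0 were higher and 0 lower at a Benjamini-Hochberg adjusted p under 0.05, and the lowest adjusted p was 0.329. An unadjusted p under 0.05 was found by edgeR for 1560 genes with higher and 1296 with lower values in Fe-deficient anthers. DESeq2 called 439 genes higher and 278 lower, limma-voom called 0 and 0, and limma on log2(TPM + 1) called 1 and 2. Without Fe-deficient 3 the lowest edgeR adjusted p was 0.0859 and 6783 genes had an unadjusted p under 0.05. Without control 1 that number was 1320, without control 2 it was 1698, and without Fe-deficient 1 it was 1559. With replicates 1 and 2 of each group alone, a choice made after the data were examined, edgeR called 89 genes higher and 3 lower.

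The group Ib bHLH transcription factors, which promote iron uptake, and the IMA peptides, which signal iron shortage, separated Fe-deficient 3 from every other library. bHLH38 (AT3G56970, TAIR10.1 chromosome 3, 21084035 to 21085245, minus strand, 2 exons) had 198 CPM (counts scaled to library size) in Fe-deficient 3, against 0.134 in Fe-deficient 1, 0.113 in Fe-deficient 2 and 0 to 0.0502 in the controls. bHLH39 had 92.5 CPM in Fe-deficient 3 and 0 counts in all controls. Against a floor of 3 counts per library this is at least 567-fold higher in that library, counting error only. bHLH100 was at 212 CPM and bHLH101 at 83.4 CPM in Fe-deficient 3. IMA1 (AT1G47400, chromosome 1, 17385707 to 17386485, plus strand, 1 exon) had 127 CPM there, against 1.95 in Fe-deficient 1, 0.510 in Fe-deficient 2 and at most 0.960 in a control. IMA3 (AT2G30766, chromosome 2, 13107583 to 13110480) had 156 CPM, 4.30 CPM and 0.340 CPM in Fe-deficient 3, 1 and 2. Reads of IMA1 and IMA2, and of bHLH38 and bHLH39, may be shared between these related genes. Such sharing was not measured, so the division within each pair is uncertain. bHLH38, bHLH39, bHLH101 and NAS4 reached the counts needed for testing in too few libraries and were not tested.

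BTS, an E3 ligase that restrains the iron-deficiency response, lies on chromosome 3 (6273966 to 6280562). It had 858 CPM in Fe-deficient 3 against 75.4 ± 4.31 (SD, n = 3) in controls, an 11.4-fold difference for this library. The phloem iron transporter OPT3 (chromosome 4, 9247302 to 9250343) had 571 CPM in Fe-deficient 3 and 67.6 in Fe-deficient 1 against 26.5 ± 10.8 (SD, n = 3), and 19.5 in Fe-deficient 2. FRO3, a mitochondrial ferric reductase, had 324 CPM in Fe-deficient 3 against 28.9 ± 4.47 (SD, n = 3). It was at 38.1 and 38.6 CPM in Fe-deficient 1 and 2, above all controls (at most 34.1 CPM). PYE, a bHLH regulator of iron homeostasis, was above the controls in all 3 Fe-deficient libraries, at 15.1, 14.5 and 46.0 CPM against 10.2 ± 1.07 (SD, n = 3). MYB72 and BTSL1 were also above all controls in each Fe-deficient library. The edgeR log2 fold changes were 3.07 (SE 0.60) for MYB72 and 1.37 (SE 0.27) for BTSL1. These were the 2 members past the threshold by edgeR when p was adjusted over the list alone, and 0 of 17 passed over all genes. Their edgeR adjusted p over all genes was 0.329. FIT, the root regulator of iron uptake, was low everywhere (0.733 ± 0.368 CPM in controls and 0.816 ± 0.246 in Fe-deficient anthers, SD, n = 3).

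The iron deficiency regulators as a list were higher in Fe-deficient anthers by camera (adjusted p = 0.00852, 15 of 17 tested members with a positive log2 fold change, median 0.30). With an estimated correlation the adjusted p was 0.525, and without Fe-deficient 3 the camera adjusted p was 0.111. Iron acquisition genes were not called (camera adjusted p = 0.676, 7 of 14 with a positive log2 fold change, 0 past the threshold over the list alone). IRT1, the root iron importer, had 24.6 ± 3.20 CPM in controls and 16.8 ± 5.64 in Fe-deficient anthers (SD, n = 3). FRO2, the root ferric reductase, was at 16.3 CPM in Fe-deficient 1 and at 1.47 and 3.40 CPM in the other two. FRO1 was higher in all 3 Fe-deficient libraries (log2 fold change 0.62, SE 0.23, edgeR adjusted p = 0.355). Iron and nicotianamine transport was not called (camera adjusted p = 0.736, 9 of 15 positive, 0 past the threshold over the list alone). Its member YSL1, a transporter of metal-nicotianamine complexes, was lower in all 3 Fe-deficient libraries, at 18.9, 11.3 and 5.71 CPM against 41.6 ± 17.8 (SD, n = 3). The log2 fold change of YSL1 was -1.80 (SE 0.52, edgeR adjusted p = 0.329), and DESeq2 called it.

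**Figure D1:**
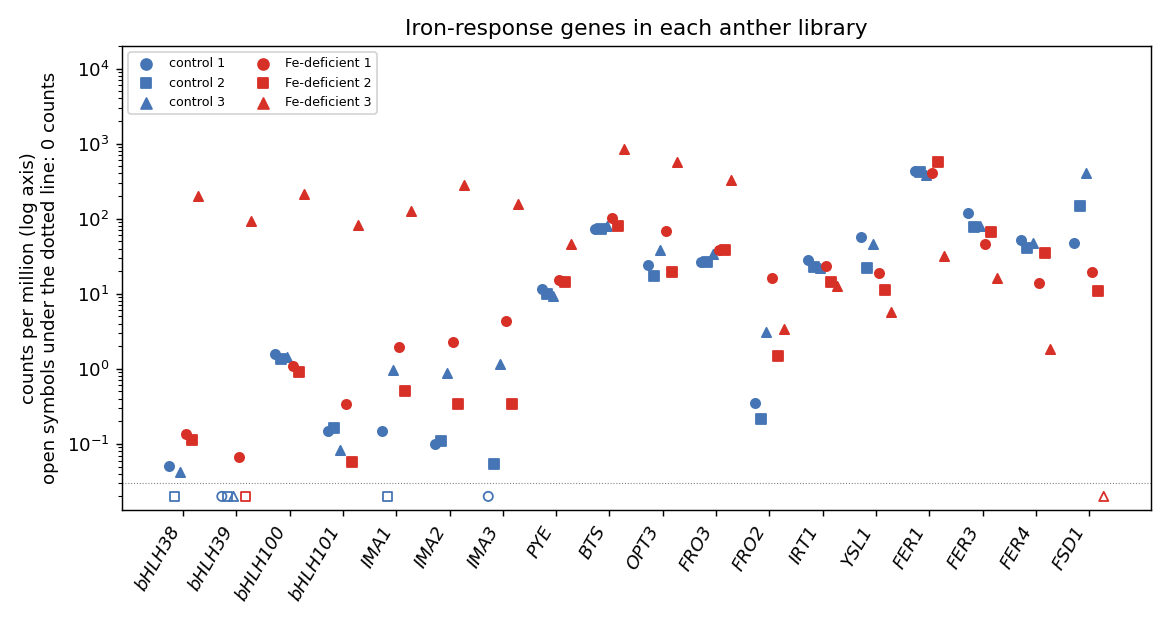
CPM of 18 iron-response genes (log axis) in each of the 6 libraries. Each symbol is 1 library, blue for control and red for Fe-deficient, and open symbols mark 0 counts. Fe-deficient 3 stands at 83.4 to 281 CPM for bHLH38, bHLH39, bHLH100, bHLH101 and the IMA genes, while Fe-deficient 2 has at most 0.907 CPM for these 7 genes.

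Iron storage showed the opposite picture in Fe-deficient 3. The ferritin FER1 (AT5G01600, chromosome 5, 227953 to 230051, minus strand, 8 exons), the plastid iron store, had 31.8 CPM in Fe-deficient 3 against 408 ± 24.7 (SD, n = 3) in controls, 12.9-fold lower in this library. It was at 409 CPM in Fe-deficient 1 and 577 CPM in Fe-deficient 2. Its edgeR log2 fold change of -0.27 (SE 0.86) became 0.27 without Fe-deficient 3. FER3 and FER4 were below all controls in each Fe-deficient library. FER4 had 13.8, 35.0 and 1.83 CPM in Fe-deficient 1, 2 and 3 against 46.8 ± 5.23 (SD, n = 3), a log2 fold change of -1.48 (SE 0.86, edgeR adjusted p = 0.453). FER3 had a log2 fold change of -1.10 (SE 0.49, edgeR adjusted p = 0.378). FER2 and VIT1, the vacuolar iron importer, had log2 fold changes of 0.32 (SE 0.34) and 0.74 (SE 0.51). The vacuolar transporter homologue VTL1 had a log2 fold change of -0.01 (SE 0.80), with 1.35 CPM in Fe-deficient 3 against 11.2 ± 0.656 (SD, n = 3). The storage list was not called (camera adjusted p = 0.230, 0.773 with an estimated correlation, 5 of 7 tested members negative, 0 past the threshold over the list alone). At the preset correlation it was called lower without Fe-deficient 2 (camera adjusted p = 0.0168) and with the late pollen mean as a covariate (0.000121). It pointed up without Fe-deficient 3 (0.709). Its median log2 difference from the controls was -2.43 in Fe-deficient 3, 0.00 in Fe-deficient 1 and 0.50 in Fe-deficient 2.

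Among superoxide and peroxide scavenging genes, the iron superoxide dismutase FSD1 (AT4G25100, chromosome 4, 12884300 to 12887011) was below every control in each Fe-deficient library. It had 19.5, 10.8 and 0 CPM in Fe-deficient 1, 2 and 3, against 47.0, 148 and 412 CPM in controls 1, 2 and 3. The 0 allows up to 0.131 CPM in that library, which is 3 counts. Its log2 fold change was -4.34 (SE 1.58, edgeR adjusted p = 0.355). The copper/zinc superoxide dismutase CSD1 had 365 ± 30.1 CPM in Fe-deficient anthers and 190 ± 114 in controls (SD, n = 3), a log2 fold change of 0.94 (SE 0.45, edgeR adjusted p = 0.391). The list as a whole was not called (camera adjusted p = 0.736, 7 of 11 positive, 0 past the threshold over the list alone).

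Genes for the outer pollen wall were lower in Fe-deficient anthers. Of 26 tested genes of the sporopollenin and pollen wall list, 25 had a negative log2 fold change, with a median of -0.96, and 18 were below all controls in each Fe-deficient library. Over the list alone 16 passed by edgeR, all lower, and 0 passed over all genes. DESeq2 called 13 of them lower over all genes. TKPR2, a reductase of the sporopollenin pathway, had 88.7 ± 26.3 CPM against 256 ± 64.6 (SD, n = 3), a log2 fold change of -1.53 (SE 0.28, edgeR adjusted p = 0.329). CYP704B1, a fatty acid hydroxylase of the same pathway, had 104 ± 33.8 CPM against 300 ± 112 (SD, n = 3). Camera called the list lower (adjusted p = 1.66e-10), and with an estimated correlation the adjusted p was 0.525. With the late pollen mean as a covariate the median was -0.51 (camera adjusted p = 2.62e-09). With that covariate and without Fe-deficient 3 it was -0.17 (0.0267), against -0.84 without Fe-deficient 3 alone. Anther and tapetum regulators were lower too. Camera gave an adjusted p of 1.22e-05 (0.525 with an estimated correlation), 15 of 17 were negative, and 9 passed over the list alone, all lower. With the late pollen covariate the camera adjusted p was 0.00345, and 0.915 when Fe-deficient 3 was left out as well. MS1, which acts late in the tapetum, had a log2 fold change of -1.14 (SE 0.24) and bHLH91 one of -1.11 (SE 0.23), both with an edgeR adjusted p of 0.329. Meiosis genes were lower by a smaller amount. The median log2 fold change was -0.33, 28 of 31 were negative, 0 passed over the list alone, and the camera adjusted p was 0.000115 (0.525 with an estimated correlation, 0.139 with the late pollen mean as a covariate). The recombinase DMC1 had 10.9 ± 1.44 CPM against 21.7 ± 8.61 (SD, n = 3), and MSH4 a log2 fold change of -1.12 (SE 0.34). The pollen coat list was not called (camera adjusted p = 0.376, 6 of 9 negative, 0 past the threshold over the list alone), with EXL4 at 1747 ± 535 CPM against 2805 ± 476 (SD, n = 3) and EXL5 at a log2 fold change of -0.66 (SE 0.24).

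Pollen maturation genes went the other way. All 25 tested late pollen genes had a positive log2 fold change, with a median of 1.51, and 7 were above all controls in each Fe-deficient library. Camera called the list higher (adjusted p = 3.55e-09, 0.525 with an estimated correlation), and 0 members passed over the list alone. The pollen tubulin TUA1 had a log2 fold change of 1.78 (SE 0.45), and the receptor kinase BUPS1 had 148 ± 79.2 CPM against 30.1 ± 23.5 (SD, n = 3). Libraries of 1 group differed widely on this list. The median against the mean of the 3 controls was -1.12, 0.43 and 0.70 in controls 1, 2 and 3, and 2.11, 2.22 and 0.46 in Fe-deficient 1, 2 and 3. Sperm lineage genes were also higher (camera adjusted p = 0.00758, 0.525 with an estimated correlation, 6 of 6 positive, 0 past the threshold over the list alone). GEX1 had 14.2 ± 5.83 CPM against 2.74 ± 2.64, and DAZ1 7.38 ± 3.53 against 2.08 ± 1.19 (SD, n = 3). The sugar supply list (camera adjusted p = 0.183, 6 of 7 positive) and the endothecium, dehiscence and jasmonate list (0.183, 12 of 14 positive) were not called, and 0 members of either passed over the list alone. The sugar transporters SWEET13 and STP11 were highest in Fe-deficient 2, at 25.6 and 72.1 CPM. AOC1, of jasmonate synthesis, had a log2 fold change of 1.25 (SE 0.38) and MYB26, which directs endothecium thickening, one of -0.48 (SE 0.15).

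**Figure D2:**
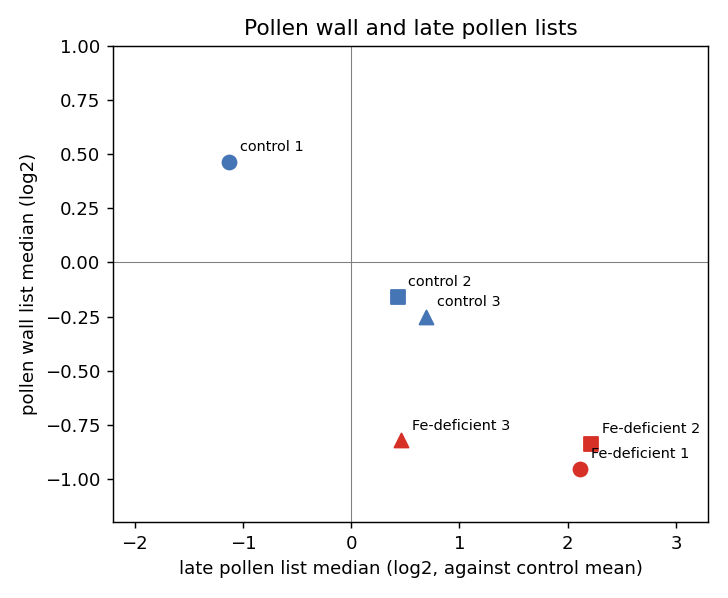
Median log2 difference from the control mean for the pollen wall list (vertical axis) against the late pollen list (horizontal axis), 1 symbol per library. The wall medians of the 3 Fe-deficient libraries lie between -0.96 and -0.82, below those of the 3 controls, while the late pollen median of Fe-deficient 3 (0.46) lies between those of control 2 (0.43) and control 3 (0.70).

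Photosynthesis genes were lower as a list (camera adjusted p = 2.03e-05, 0.525 with an estimated correlation). Of 44 tested, 35 had a negative log2 fold change, with a median of -0.41, and 0 passed over the list alone. Below all controls in each Fe-deficient library were 16 of the 44, where 10.4% of all tested genes were. Among the 16 were the photosystem I subunits PSAK (log2 fold change -0.59, SE 0.13) and PSAF (-0.80, SE 0.17), and DESeq2 called both. Going against the list, 4 of the 44 were above all controls in each Fe-deficient library, where 9.95% of all tested genes were. These were LHCA4, LHCB1.1, LHCB1.2 and LHCB2.1, light-harvesting proteins chosen after their values were seen. Reads of the LHCB1 copies can be shared. The list medians were -0.54, -0.54 and -0.11 in Fe-deficient 1, 2 and 3 and -0.10, -0.14 and 0.23 in controls 1, 2 and 3, so Fe-deficient 3 lay within the control range. Chlorophyll and heme synthesis genes were lower as well (camera adjusted p = 0.00161, 0.525 with an estimated correlation, 16 of 18 negative, 0 past the threshold over the list alone). Their medians were -0.63, -0.58 and -0.02 in Fe-deficient 1, 2 and 3, the last within the control range of -0.20 to 0.18. GUN4, which activates magnesium chelatase, had 12.9 ± 1.77 CPM against 22.4 ± 4.69, and DVR, a chlorophyll reductase, 16.8 ± 5.49 against 34.2 ± 4.65 (SD, n = 3). Iron-sulfur cluster assembly genes were not called (camera adjusted p = 0.514, 18 of 29 negative, 0 past the threshold over the list alone). In Fe-deficient 3, 3 members of this list fell by at least 1 on the log2 scale and 0 rose. Its scaffold gene ISU1 had a log2 fold change of 0.55 (SE 0.17) and SUFE3 one of -0.49 (SE 0.21). Mitochondrial iron enzymes were not called (camera adjusted p = 0.183, 0.690 with an estimated correlation, 7 of 8 positive, 0 past the threshold over the list alone). Without Fe-deficient 3 they were called higher at the preset correlation (camera adjusted p = 0.000962). AOX1A, the alternative oxidase, had 120 CPM in Fe-deficient 3 against 16.8 ± 1.90 (SD, n = 3), and the aconitase ACO1 a log2 fold change of 0.39 (SE 0.17). Other metal homeostasis genes were not called (camera adjusted p = 0.736, 9 of 16 negative, 0 past the threshold over the list alone). The zinc exporter HMA2 had a log2 fold change of -0.52 (SE 0.17) and the copper importer COPT1 one of 0.90 (SE 0.37).

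All 3 tested genes of the senescence and defence list were higher in each Fe-deficient library, and all 3 passed over the list alone, with 0 over all genes. The list was too small for camera. SEN1, a senescence-associated gene, had 76.1 ± 21.5 CPM against 16.6 ± 7.73 (SD, n = 3), with an edgeR adjusted p of 0.329. PR5, a defence protein, had a log2 fold change of 2.65 (SE 0.53, edgeR adjusted p = 0.329). The heat shock list was not called (camera adjusted p = 0.974, 3 of 5 negative, 0 past the threshold over the list alone). HSP17.4 had a log2 fold change of 2.29 (SE 0.91). HSFA2 stood at 23.0 CPM in control 1 and at no more than 2.69 CPM elsewhere.

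Markers of other floral parts varied between libraries of 1 group. AP1, of the floral meristem, sepals and petals, was chosen after its values were seen. It had 84.7 CPM in control 3 and 98.5 CPM in Fe-deficient 3, and between 10.9 and 18.8 CPM in the other 4 libraries. Fe-deficient 3 is the library with the high iron-deficiency genes. The meristem, sepal and petal list was too small for camera, with 3 of 4 tested members positive and 0 past the threshold over the list alone. WUS had a log2 fold change of 0.87 (SE 0.37) and LFY one of 0.89 (SE 0.69). WUS did not follow AP1, with 141 and 105.5 CPM in Fe-deficient 1 and 2, 50.4 in Fe-deficient 3 and 52.8 in control 3. The carpel and ovule list was not called (camera adjusted p = 0.0986, 0.525 with an estimated correlation, 5 of 6 negative, 0 past the threshold over the list alone). It was called lower without control 1 (0.0445), control 3 (0.00742) or Fe-deficient 1 (0.0138). SHP1 had 1.77 ± 0.467 CPM against 4.05 ± 1.93 (SD, n = 3), and SHP2 a log2 fold change of -1.28 (SE 0.52).

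**Figure D3:**
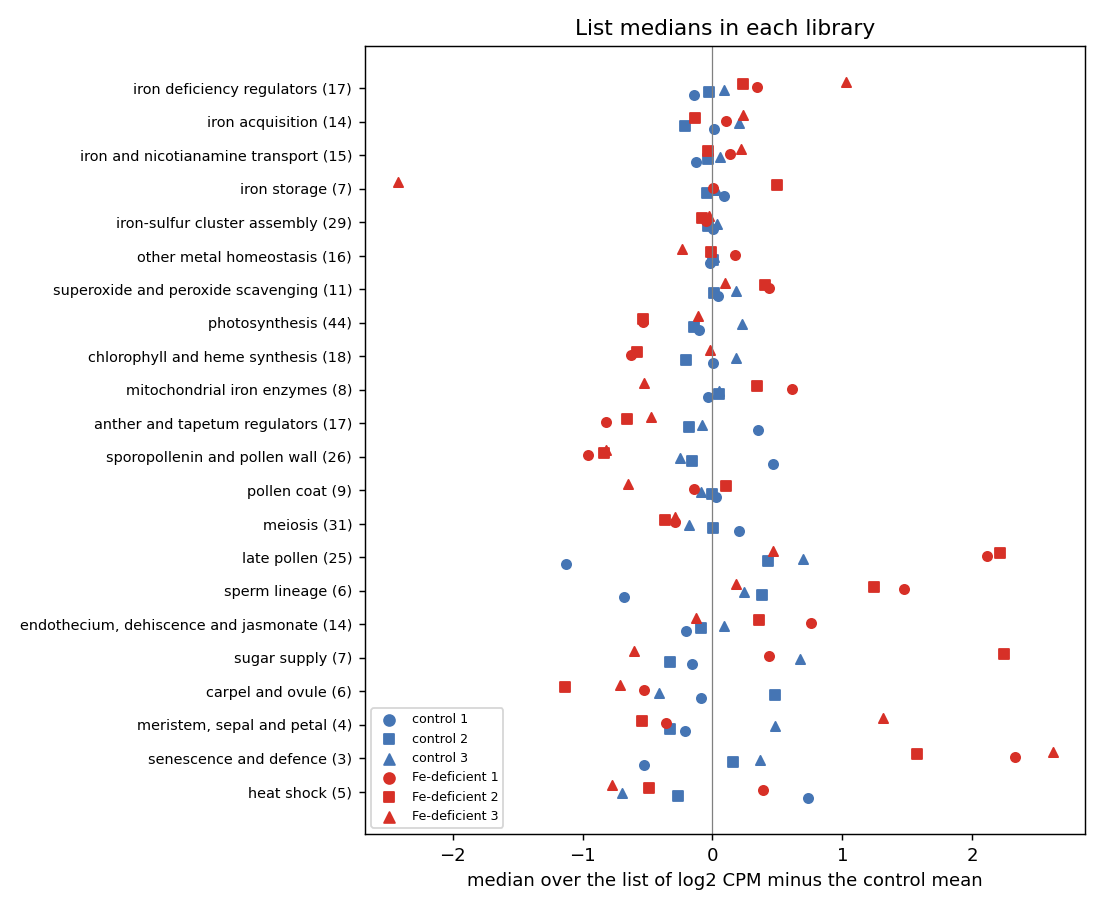
Median log2 difference from the control mean over the tested genes of each fixed list (number in brackets), 1 symbol per library, blue for control and red for Fe-deficient. The pollen wall medians of the Fe-deficient libraries lie between -0.96 and -0.82, and the iron storage median of Fe-deficient 3 lies at -2.43.

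The libraries of each group differed strongly in more than iron genes. The first principal component held 58.0% of the variance and ran from control 1 (-114) to Fe-deficient 1 (82.7) and Fe-deficient 2 (77.4), with Fe-deficient 3 at 3.90 and control 3 at 0.330. The second held 22.6% and set Fe-deficient 3 apart at -86.9. Pearson's r of log CPM across genes, which are not independent replicates, was 0.966 between Fe-deficient 1 and 2, and 0.906 and 0.898 between Fe-deficient 3 and these. Fe-deficient 3 had higher values with control 3 (0.953) and control 2 (0.911). On log2(TPM + 1) the median shift of a gene from the main fit was -0.21. There the medians of the iron acquisition, transport, scavenging, sugar supply and meristem lists changed sign. The transport median also changed sign with upper-quartile factors (-0.017). The direction of these lists therefore depended on the scaling. All 3 Fe-deficient values lay above all 3 controls for 9.95% of tested genes and below them for 10.4%, where chance gives 10% in both directions together. These were 4331 genes, and the split of control 1, control 3 and Fe-deficient 3 against the rest fully separated 4739 genes. With 3 libraries against 3, an exact two-sided permutation test of a single gene cannot give a p below 0.1.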

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

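The fits without doubted libraries, the pollen covariate and DESeq2 without Cook's filter were added after the data were seen. Most alternatives left both counts of genes past the threshold at 0. Others did not, for causes that were not tested. DESeq2 gave 439 higher and 278 lower (469 and 282 without Cook's filter), limma on log2(TPM + 1) gave 1 and 2, on log2(TPM + 0.1) 3 and 5, and with no filter 0 and 2. Replicates 1 and 2 of each group alone gave 89 and 3. Upper-quartile factors gave 1158 higher and 1759 lower genes at an unadjusted p under 0.05, against 1560 and 1296 with TMM. For limma on log2(TPM + 1) these numbers were 788 and 2825, with a median shift over genes of -0.21 on the log2 scale. Of 8 lists called, 0 remained with an estimated correlation and 0 by fry, and leaving out 1 library gave 8 to 9 lists. With the late pollen mean as a covariate, the late pollen list (adjusted p = 0.506) and the sperm lineage list (0.871) lost their call and pointed the other way, which for the late pollen list follows from the covariate itself. With that covariate and Fe-deficient 3 left out, 5 lists were called, the meiosis list pointed up (adjusted p = 0.973) and the heat shock list was called higher (5.1e-07). Without control 1 and Fe-deficient 3 the heat shock list was higher (adjusted p = 0.0476). Calls were gained on log2(TPM + 1) for endothecium, dehiscence and jasmonate (0.0429) and sugar supply (0.0381), with no low-count filter for carpel and ovule (0.0173), and with the late pollen covariate for other metal homeostasis (0.0236) and pollen coat (0.0219), both lower. Depth limits genes near the floor of 3 counts, as in the controls for bHLH38 and bHLH39.

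Of 680 values of named genes under alternatives, 653 kept direction and call, 17 passed the threshold (all by DESeq2) and 10 changed sign. Leaving out each library in turn, the log2 fold change ranged for FIT from -0.17 to 0.56, for bHLH100 from -0.54 to 6.20, for FER1 from -0.89 to 0.27, for VTL1 from -0.82 to 0.52, for LFY from -0.18 to 1.28 and for HSFA2 from -3.34 to 0.48. VTL1 was at 0.007 by DESeq2 and 0.002 with DESeq2 size factors. The replicate block gave 0 genes higher and 0 lower and 8 lists. Libraries with the same number deviated together for number 2 (correlation 0.427), where each correlated best with the other, and not for numbers 1 and 3 (-0.179 and -0.117), so the numbers were not taken to pair them.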

Other observations

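The tests in this part were chosen after the results were seen, except the splits counted with DESeq2. The genes named next are a selection, made after the data were seen, from those with the lowest edgeR p. None passed the threshold (edgeR adjusted p = 0.329), and others with as low a p are not described. IVD, of leucine breakdown, had 81.6 ± 5.73 CPM against 37.1 ± 4.09 (SD, n = 3), and MGL, methionine gamma-lyase, 87.0 ± 20.9 against 38.2 ± 2.59. RD26, a NAC factor of the abscisic acid response, had a log2 fold change of 2.04 (SE 0.29), and HIPP22, a metal-binding-domain protein, one of 2.77 (SE 0.25). QRT1, a pectin methylesterase needed for pollen grains to separate, had 15.7 ± 2.17 CPM against 36.0 ± 6.50 (SD, n = 3).

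Iron-deficiency genes were high in Fe-deficient 3, where bHLH38, bHLH39, bHLH100, bHLH101 and IMA1 to IMA3 summed to 1150 CPM. A swap with a control cannot be told apart. The highest control sum was 4.55 CPM, but the Fe-deficient sums ran from 2.27 to 1150 CPM, so a library like Fe-deficient 2 among the controls would not stand out. RNA of sepals, petals or leaves added to this library would only dilute the storage genes, and would dilute pollen wall and coat genes too. The storage median of -2.43 in Fe-deficient 3 is the fall itself, so it is no separate test. The wall (-0.82) and pollen coat (-0.65) medians there fell less. This argues against dilution as the whole of the fall of ferritins. For the rise of the iron-deficiency genes, added RNA cannot be told apart, since AP1 was at 98.5 CPM in Fe-deficient 3, above all controls. The photosynthesis median (-0.11) was within the control range, but control 3, also high in AP1, set the top of that range (0.23). Of that list, RBCS1B and RBCS2B were at 152 and 254 CPM in Fe-deficient 3 and at 203 and 532 CPM in control 3. Elsewhere they reached at most 28.65 and 63.4 CPM. Of its 44 members, 5 rose by at least 1 on the log2 scale in Fe-deficient 3 and 4 fell by as much. Control 3 had 84.7 CPM of AP1 and a sum of 4.55 CPM over the 7 genes, but tissue of plants with iron does not show what tissue of plants without it would add. A different anther stage cannot be told apart, since the lists disagree. The late pollen median of 0.46 lay inside the wide control range (-1.12 to 0.70), as did the sperm lineage (0.18) and endothecium (-0.13) medians. Those of the wall (-0.82), anther and tapetum (-0.48), pollen coat (-0.65) and meiosis (-0.29) lists lay below all controls. A stronger iron shortage in the plants of this library may be involved, which was not tested.

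Fe-deficient 2 had a sum of 2.27 CPM over the same 7 genes, inside the control range of 1.69 to 4.55 CPM. Plants that had iron could give this. The iron storage median was 0.50 in this library, above all controls, with 4 of 7 tested members above the control range and 2 below it. Of 17 tested iron deficiency regulators, 7 were above the control range and 4 below it. The 4 below include bHLH100 (0.907 CPM against at least 1.36). Some members of any list lie outside the control range by chance, and the share over all genes was not counted. Those above include BTSL1 (15.9 CPM against at most 7.22), PYE (14.5 against at most 11.4) and MYB72 (0.851 against at most 0.326), and FSD1 and YSL1 were below. These 5 had been seen to differ in all 3 Fe-deficient libraries, so they are no independent test. A wrong label stays open and cannot be told apart from a weaker shortage.

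The pollen wall list median was below all controls in each Fe-deficient library. An error of scaling would move all genes alike, and the late pollen list median lay 2.47 above that of the wall list on the log2 scale. That gap includes the late pollen rise (median 1.51), so it does not show that the wall list itself fell. The wall median was -0.95 with DESeq2 size factors and -1.04 with upper-quartile factors. In Fe-deficient 1 and 2, anthers further along could account for most of the fall of the wall list. Without Fe-deficient 3, the late pollen covariate moved the wall median from -0.84 to -0.17, though camera still called the list lower (adjusted p = 0.0267). The late pollen medians of both libraries (at least 2.11) lay above all controls. The covariate therefore nearly restates the group in that fit, and cannot separate stage from the iron treatment. In Fe-deficient 3 late pollen genes were above both controls 2 and 3 for 7 of 25 members and below both for 12, while 25 of 26 wall genes were below both. The wall median there lay at -0.66 from the line through the 3 controls (wall against late pollen), against -0.14 and 0.02 in Fe-deficient 1 and 2. With a late pollen median of 0.46, inside the control range, this argues against a later stage alone, though the line rests on 3 points. RNA of other tissue, left open above for this library, would lower both lists. A later stage with such dilution therefore stays possible. The distance from the line replaced an earlier measure, which could not decide, after both results had been seen. A different mix of stages, dilution and the iron treatment itself were not tested and stay open.

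The 6 libraries split into 3 and 3 in 10 ways, too few for a share under 0.05. The edgeR count of genes was 0 in the real split and at most 0 in the others, so 10 of 10 splits gave as many, which any split does for a count of 0 and which says nothing about chance. At an unadjusted p under 0.05 edgeR gave 2856 genes in the real split and 3605 in the split of control 1, control 3 and Fe-deficient 3 against the rest. With DESeq2 the real split called 717 genes and the highest other 470, and 1 of the 10 splits gave as many. Camera called 8 lists in the real split and 9 in the highest other, and 6 of the 10 splits gave as many.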
